A study of Pyrus communis with 8 samples.

How the data were processed

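Total RNA of pear fruit was labelled with Cy3 and hybridised to single-colour Agilent arrays. Per the labels, RNA of -7 and 0 DAFB came from fruit receptacle (young flesh) by one extraction method, with 10 to 50 ng labelled, and RNA of 30 to 182 DAFB came from fruit flesh by another, with 500 ng labelled. The deposited scanner files hold spot intensity values from Feature Extraction 10.7.1.1 with the protocol GE1_107_Sep09, per the file headers. The processed intensity is that software's background-corrected signal, and spots carry its marks for signal well above background, saturation and outliers. The authors' deposited value table holds 1 log2 value per probe and stage. Set against the scanner values, 99.94% of its entries lay within 0.01 of the log2 processed signal scaled to the 75th percentile, averaged per stage and centred on the probe's mean over the 25 arrays. Its column medians were 0.133, 0.591, -0.245, 0.118, -0.009, -0.104, -0.159 and -0.437 from the earliest to the latest stage. Scale, centring and direction are therefore known, and it gave the same direction for all 32 named results.

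The log2 processed signal of each array was reduced by the log2 of its 75th percentile over the pear spots, which was 374.1 to 1986 in signal units. Outlier spots (436 over all arrays) were left out, saturated spots would have been kept, and the 2 spots of a probe (10 for 15 probes) were averaged. Different probes of a clone were kept apart. A probe was tested if it was well above background on every array of at least 1 stage, which held for 17014 of 21681 probes (78.5%). Stages were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), all 25 arrays sharing 1 estimate of spread, with Benjamini-Hochberg adjustment at 0.05 within each comparison. The 7 consecutive steps, 150 vs 30 DAFB and an F-test over the 8 stages were fixed before the data were examined. Tables were handled with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and drawn with matplotlib 3.10.9.

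On data simulated from the real spread with 200 changed probes, the fit recovered 69% of 2-fold changes in 0 vs -7 DAFB, 66% in 30 vs 0 DAFB, 68% in 150 vs 30 DAFB and 62% in 182 vs 150 DAFB, each over 17014 probes. Of changes of 0.5 on the log2 scale it recovered 19%, 20%, 28% and 29% in that order, and 2.22%, 4.44%, 4.95% and 5.21% of the calls were false. In the real data 37.0% to 73.4% of probes were called in these comparisons, far more than the 200 simulated. The simulated spread was also drawn independently for each array and probe, without the correlation of arrays on a slide. These shares may therefore not carry over to the real data.

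Named probes followed a rule set before the data were examined: the 2 largest rises and the 2 largest falls of each comparison, among probes past the threshold whose arrays did not overlap between the stages. Because signals below background have no order, they also had to be well above background on every array of both stages. That requirement was added when the values were ranked. In several comparisons it left out larger changes, of probes not well above background at either the earlier or the later stage. The named probes are therefore not the largest of all changes. Gene names were sought in a table of the drPyrComm1.1 assembly, and 0 probe names matched. The 36 gene lists fixed before the data were examined could therefore not be tested. Probe identifiers fall into 5 main name classes, NFR (11524 probes), NFW (4137), NLE (3373), DIT (1789) and sequence accessions (855), whose abbreviations are not explained in the sources used here.

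The arrays came from 12 slides and 3 scan days. Scan day 1 held -7 and 0 DAFB, day 2 held 30 DAFB and day 3 the later stages, so 30 vs 0, 60 vs 30 and 150 vs 30 DAFB cross days. Only slide 5 held more than 1 stage, and the stages -7, 60, 120 and 150 DAFB spanned several slides, so slide was fitted as a random block. Scan day could not be fitted as a block, because each stage lies within a single day, and the steps within a day were refitted on that day's arrays. No array pair held identical values. Same-numbered arrays of 150 and 30 DAFB deviated together, with correlations of 0.205, 0.129 and 0.121 across probes, which meets the rule set for pairing. Nothing in the labels ties the numbers to shared material, and in no other comparison did all pairs exceed 0.1.

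Alternatives set before the data were examined were quantile normalization, median scaling, 2 other filters on dim probes, eBayes without a trend, array quality weights, the arrays of the compared stages alone, the replicate number and the slide as blocks, a 2-fold minimum and leaving out each array. Normexp with an offset of 50 had been planned on the mean signal and was run on the median spot signal and median local background, since the scanner tables used here hold no mean signal column. Added after seeing the data were scaling on the 6 brightest spike-in controls, fits within a scan day, a 4-fold minimum for the sets by stage and a looser rule for detection, under which at least 0.5 of the spots of 1 stage and fewer than 0.1 of those of the other were well above background. Also added were fits without 2 arrays picked by eye, 0 DAFB replicate 1 for its outlier spots and 150 DAFB replicate 3 for its raised low signals, and fits without the 3 arrays of lowest quality weight, which are others: 120 DAFB replicate 1 (0.118), 150 DAFB replicate 1 (0.188) and -7 DAFB replicate 3 (0.331).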

Results

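Transcript levels in the fruit flesh of the European pear (Pyrus communis) cultivar La France were followed from before bloom to the ripe fruit. The 8 stages were -7, 0, 30, 60, 90, 120, 150 and 182 days after full bloom (DAFB). Fruit was harvested at 150 DAFB, and the 182 DAFB fruit had been chilled after harvest (12 days, 2 °C) and ripened for 20 days at 15 to 20 °C. Each stage was measured on 3 arrays, except 60 DAFB with 4, which gives 25 single-colour arrays in all. Each array held 43482 spots for 21681 pear probes. The probes belong to 12099 name stems, called clones here, and 9582 clones had 2 probes. Between 28236 and 34134 spots per array were well above background, 64.9% to 78.5% of the spots, and 0 spots were saturated. The number of arrays limits the precision of all comparisons. The titles number the arrays as replicates, and nothing states that they came from separate fruits or trees, so p-values measure only the spread between these arrays, which may be technical.

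Probes are given by their identifiers because 0 of the probe names matched the reference gene table used here. Levels are log2 signals relative to the 75th percentile of each array, so a rise or fall is relative to that percentile.

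Arrays of a stage resembled each other more than arrays of different stages, but only narrowly at the extremes. Pearson's r between arrays of a stage, across probes, was 0.97301 to 0.997 with a median of 0.992. The highest r between arrays of different stages was 0.97288. Probes are not independent replicates. The first principal component held 54.0% of the variance and the second 21.7%. Among 17014 probes tested, 16865 (99.1%) changed across the 8 stages in limma's moderated F-test, of which 15490 ranged at least 2-fold between stage means, 10679 at least 4-fold and 4436 at least 16-fold. The correlation of stage means was 0.970 between -7 and 0 DAFB, 0.846 between 0 and 30 DAFB, 0.973 between 120 and 150 DAFB and 0.896 between 150 and 182 DAFB. The lowest correlation, 0.608, was between 0 and 182 DAFB. Scan day, extraction method and tissue label were constant within a stage, and slides were largely separate between stages. All values in this paragraph therefore hold any effect of these together with that of stage.

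**Figure D1:**
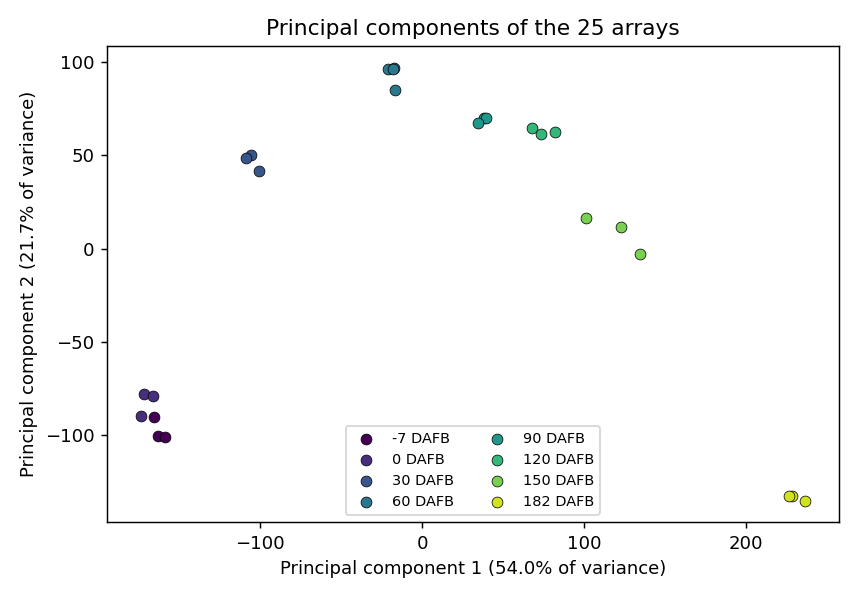
The first 2 principal components of the 25 arrays, with the share of variance on each axis and 1 point per array coloured by stage in DAFB. The 182 DAFB arrays lie between 226.7 and 236.8 on the first component, and the -7 and 0 DAFB arrays lie between -174.0 and -158.7.

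Of the 10679 probes ranging at least 4-fold, 2684 (25.1%) had their highest stage mean at 0 DAFB and 2426 (22.7%) at 182 DAFB, against 362 (3.39%) at 150 DAFB. The lowest stage mean lay at 182 DAFB for 4053 of them (38.0%). These ranges and ranks used all stage means, also those below background, which have no order. DITSSH188, for example, lay at -6.75 at 0 DAFB and -8.88 at 30 DAFB, above background on 0 arrays of either stage. Part of these shares may therefore reflect the background level of the arrays. Probes at least 2-fold above each other stage numbered 961 at 182 DAFB (663 clones), 520 at 30 DAFB (361 clones), 194 at 0 DAFB and 159 at -7 DAFB. Probes at least 2-fold below each other stage numbered 2248 at 182 DAFB (1561 clones) and 316 at 30 DAFB. Direction at 182 DAFB depended on the scaling: 2004 probes were highest and 1548 lowest there after scaling each array to its median. With normexp background correction 1167 probes were lowest at 182 DAFB. The sets of the earlier stages depended on the processing too. Spike-in scaling gave 1429 highest probes at 30 DAFB, 12 at 0 DAFB and 831 at -7 DAFB, and 32 lowest at 30 DAFB. Normexp gave 327 highest at 30 DAFB, 84 at -7 DAFB and 161 lowest at 30 DAFB. At 0 DAFB 545 were highest without the filter on dim probes and 122 with median scaling. Among probes well above background on all arrays, 531 were highest at 182 DAFB, 118 at 30 DAFB, 62 at 0 DAFB and 59 at -7 DAFB, and 1223 were lowest at 182 DAFB and 202 at 30 DAFB. With a 4-fold minimum 355, 285, 17 and 22 were highest at these 4 stages, and 1154 and 52 were lowest at 182 and 30 DAFB. From 30 to 182 DAFB, 469 probes rose in mean at each step and 816 fell at each step, with at least a 2-fold range and a stage effect.

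**Figure D2:**
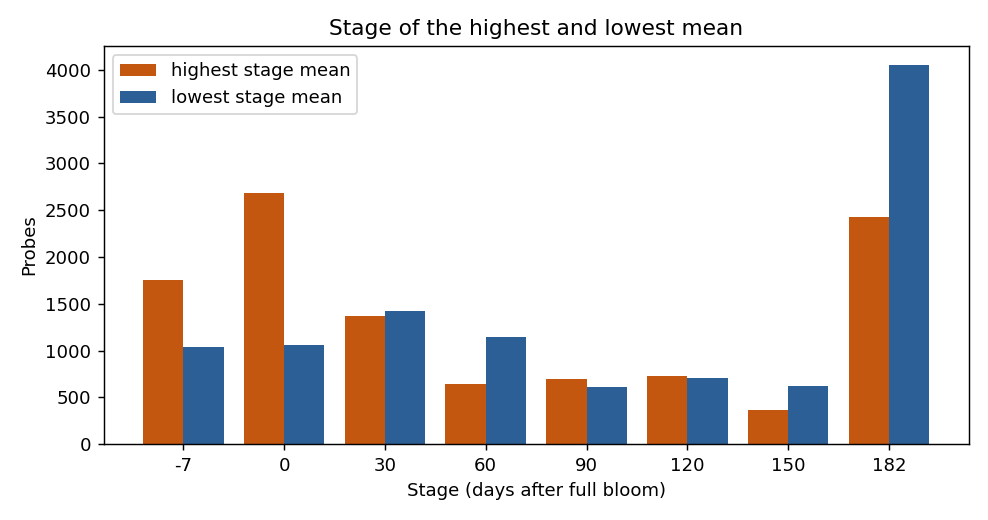
Number of probes (y axis) whose highest or lowest stage mean fell at each stage in DAFB (x axis), for the 10679 probes ranging at least 4-fold. The 182 DAFB stage held 2426 highest and 4053 lowest means. Stage means below background were ranked too, although they have no order.

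The choice of scaling moved the median of all probes, and the share of higher calls with it. After median scaling the median log2 change moved from -0.25 to -0.01 in 30 vs 0 DAFB, from -0.01 to 0.29 in 60 vs 30 DAFB, from -0.02 to -0.16 in 90 vs 60 DAFB, from -0.07 to 0.10 in 150 vs 120 DAFB, from 0.06 to 0.35 in 150 vs 30 DAFB and from -0.09 to 0.31 in 182 vs 150 DAFB. Quantile normalization gave -0.01 in 30 vs 0 DAFB, 0.17 in 150 vs 30 DAFB and 0.06 in 182 vs 150 DAFB. Scaling on the spike-in controls, an alternative chosen after seeing the data, gave medians of -0.95 in 0 vs -7 DAFB, 1.23 in 30 vs 0 DAFB, -1.79 in 60 vs 30 DAFB, 0.64 in 90 vs 60 DAFB, 0.43 in 120 vs 90 DAFB, -0.22 in 150 vs 120 DAFB, -0.75 in 150 vs 30 DAFB and 0.10 in 182 vs 150 DAFB. The named probes below kept their direction under all of these scalings.

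From -7 to 0 DAFB, around bloom, 3389 probes rose and 2899 fell, 1238 and 876 of them at least 2-fold. The largest rises measured on both sides were NFR6_08_75mm, from -2.56 ± 0.47 to 5.44 ± 0.06 (log2, SD, n = 3), and NFR6_14_60tc, which rose by 7.97. The second probe of that clone, NFR6_14_60mR2007a, rose by 2.68. Falls too were ranked only among probes measured on both sides, whereas 19 of all probes past the threshold fell at least 16-fold. The largest falls were NFW1_05_96tc, which fell by 4.07 ± 0.23 (SE), and NFR6_19_53mm, which fell by 3.95 ± 0.25 while the other probe of its clone fell by 3.93. Both probes of a clone rose in 995 clones and fell in 869, and moved in opposite directions in 30, among 7107 clones with both probes tested. Both stages shared the extraction method, the RNA input range and the scan day, but no slide. With the slide as a random block 3204 probes changed. Scaling on the spike-in controls called 11150 probes, 2.38% of them higher against 53.9%. The share was 76.2% with normexp, which called 9325, and 66.5% without the filter on dim probes.

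From 0 to 30 DAFB, bloom to young fruit, 4733 probes rose and 7647 fell, 2518 and 4582 of them at least 2-fold. DITK91317 rose from -2.86 ± 0.61 to 6.07 ± 0.22 (log2, SD, n = 3) and NFR6_13_26mm from -3.07 ± 0.18 to 5.76 ± 0.19. NFR2_05_49mS2007a fell by 11.07 ± 0.81 (SE) and AB204875.1 fell by 7.63 ± 0.30. NFR2_05_49cc, the other probe of the former clone, fell by 12.31. Both probes rose in 1468 clones and fell in 2512, and moved oppositely in 454. At 30 DAFB 862 probes were well above background on each array that were not so on any array of 0 DAFB. Of these, 276 were at least 2-fold higher by the lower bound. The reverse held for 82 probes, 136 without 0 DAFB replicate 1 and 190 under the looser detection rule, and each of the 82 was at least 4-fold lower by the bound. Such a bound sets the mean of the brighter stage against, on each array of the dimmer stage, the higher of the probe's own signal and the lowest signal well above background. Extraction method, RNA input, tissue label, scan day and slide all changed at this step, so none of them can be told apart from stage. Among the changed probes 38.2% were higher, against 49.2% with median scaling, 49.5% with quantile normalization and 88.1% with spike-in scaling, and against 25.7% with normexp and 28.7% without the filter on dim probes.

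The measured steps from 60 to 90 and 120 DAFB were smaller than that from 30 to 60 DAFB. Only the latter crossed scan days, so an effect of scan day on this ranking cannot be told apart from stage. The root mean square log2 change was 1.43 in 60 vs 30, 0.96 in 90 vs 60, 0.84 in 120 vs 90 and 0.81 in 150 vs 120 DAFB. From 30 to 60 DAFB 5327 probes rose and 5707 fell, and 908 probes well above background on each 30 DAFB array were so on no 60 DAFB array, 286 of them at least 2-fold lower by the bound. NFR6_14_94tc rose by 8.99 ± 0.24 (SE) and NFR6_04_37mR2007a by 7.81 ± 0.18, and NFR6_04_37mm of the same clone rose by 7.65. NFW2_36_34tc fell by 9.26 ± 0.31 and NLE1_12_41mm fell by 9.08 ± 0.30. From 60 to 90 DAFB 5226 probes rose and 4543 fell, with rises of 6.29 ± 0.45 in NFR6_05_96mR2007a and 5.06 ± 0.39 in NFR1_18_61cc. The other probes of these clones rose by 4.06 and 4.91. DQ901397.1 fell by 5.93 ± 0.64 and NFW1_02_59mR2007a fell by 5.35 ± 0.60. Both probes rose in 1550 clones and fell in 1249, and moved oppositely in 437. Clones moving oppositely numbered 215 in 60 vs 30, 52 in 120 vs 90 and 17 in 150 vs 120 DAFB. From 90 to 120 DAFB 3776 probes rose and 3915 fell. NFR6_18_79tc rose by 6.33 ± 0.25 and NFR6_04_83tc by 5.92 ± 0.28, and NFR1_18_61cc, raised at 90 DAFB, fell by 5.26 ± 0.41 together with NFR1_18_61mS2007a, which fell by 5.22 ± 0.41. From 120 to 150 DAFB 2518 probes rose and 2917 fell. NFR6_08_81mm rose by 6.71 ± 0.62 and NLE1_02_70cc by 6.57 ± 0.46, whereas NFR2_24_64tc fell by 5.01 ± 0.30 and NFR2_24_64mR2007a of the same clone fell by 4.99 ± 0.28.

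The 60 vs 30 DAFB step crossed scan days, and the 3 later steps lay within scan day 3. In none of these steps did the compared stages share a slide. Of changed probes in 60 vs 30 DAFB 48.3% were higher, against 66.6% with median scaling, 67.7% with normexp, 59.9% without the filter on dim probes and 2.65% with spike-in scaling. In 90 vs 60 DAFB the share was 53.5%, against 41.7% with median scaling, 41.6% with normexp and 90.7% with spike-in scaling. In 120 vs 90 DAFB it was 49.1%, against 87.5% with spike-in scaling, which called 4618 probes, and with the slide as a random block 4626 probes changed in place of 7691. In 150 vs 120 DAFB the share was 46.3%, against 67.0% with median scaling and 29.4% with spike-in scaling. That last setting called 2029 probes, and the fit on these stages' arrays alone called 2484 in place of 5435. Slide 5 held 1 array of 60 DAFB and 2 of 120 DAFB: of 4104 probes differing at least 2-fold there, 4003 had the same sign of change between the arrays on other slides. Over all tested probes these changes correlated with Pearson's r of 0.839. The comparison, 120 vs 60 DAFB, is none of the steps above. Its 120 DAFB side on other slides was replicate 1 alone, the array of lowest quality weight.

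Between young fruit at 30 DAFB and harvest at 150 DAFB, 6469 probes rose and 6016 fell, 3548 and 3767 of them at least 2-fold. NFR6_14_94tc rose from -6.43 ± 0.13 to 5.37 ± 0.25 (log2, SD, n = 3), having reached 6.01 ± 0.07 by 90 DAFB. L09264.1 rose from -6.15 ± 0.79 to 5.39 ± 0.16. Both probes of clone NFR2_24_64 fell from high levels: NFR2_24_64tc from 4.96 ± 0.19 to -6.12 ± 0.37 and NFR2_24_64mR2007a from 4.87 ± 0.15 to -6.23 ± 0.23. Both probes rose in 2315 clones and fell in 2055, and moved oppositely in 234. At harvest 166 probes were well above background on each array and on no 30 DAFB array, of which 150 were at least 2-fold higher by the bound, and the looser rule gave 373. The reverse held for 587 probes, of which 508 were at least 2-fold lower by the bound. Scan day and slide differed between these stages and cannot be told apart from stage. Among changed probes 51.8% were higher, against 63.0% with median scaling and 17.9% with spike-in scaling.

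**Figure D3:**
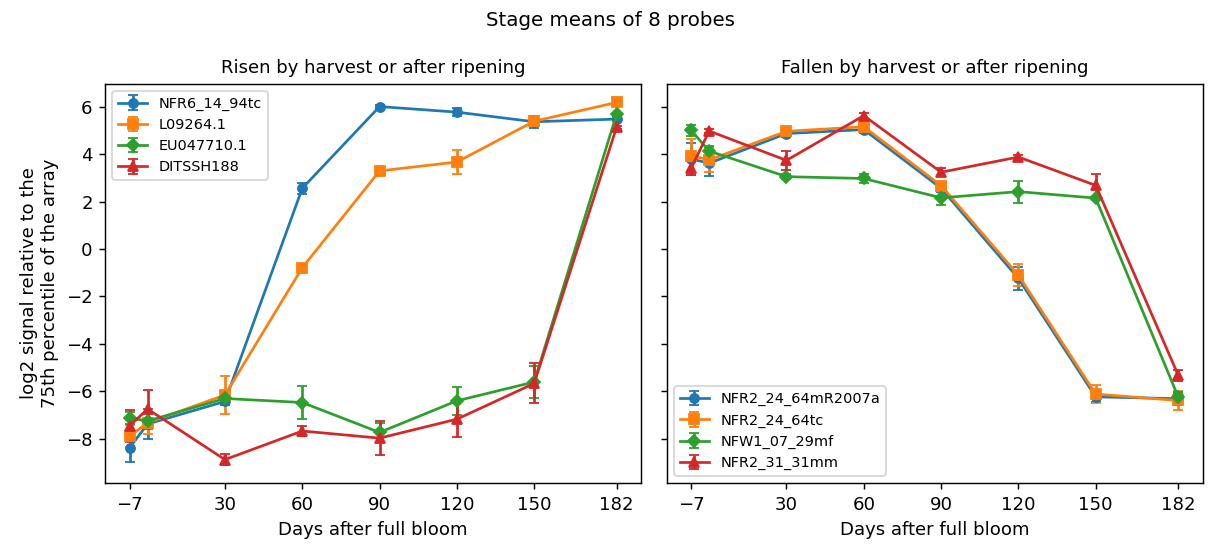
Stage means (log2 relative to the 75th percentile of the array, y axis) of 8 probes against days after full bloom (x axis), with bars of 1 SD over 3 arrays, 4 at 60 DAFB. EU047710.1 and DITSSH188 stay below -5 until 150 DAFB and reach 5.69 and 5.14 at 182 DAFB.

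After cold storage and ripening, compared with harvest, 4706 probes rose and 6068 fell, 1971 and 3645 of them at least 2-fold. EU047710.1 rose from -5.61 ± 0.68 to 5.69 ± 0.04 (log2, SD, n = 3) and DITSSH188 from -5.67 ± 0.85 to 5.14 ± 0.07. NFW1_07_29mf fell from 2.15 ± 0.06 to -6.23 ± 0.22 and NFR2_31_31mm from 2.68 ± 0.49 to -5.31 ± 0.23, and the other probe of the latter clone fell by 7.98. Both probes fell in 1976 clones, rose in 1586 and moved oppositely in 198. At 182 DAFB 519 probes well above background on each harvest array were so on no array, 434 of them at least 2-fold lower by the bound, and 95 probes went the other way, 85 of them at least 2-fold higher. Under the looser detection rule these counts were 988 and 174. Among the 519, 283 probes of 225 clones were well above background on each array of the 7 other stages. Both stages were scanned on the same day but shared no slide, so slide cannot be told apart from stage. Median scaling turned the balance of calls: 43.7% of changed probes were higher in the main scaling, 64.2% with median scaling and 52.5% with quantile normalization. Spike-in scaling called 7145 probes.

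**Figure D4:**
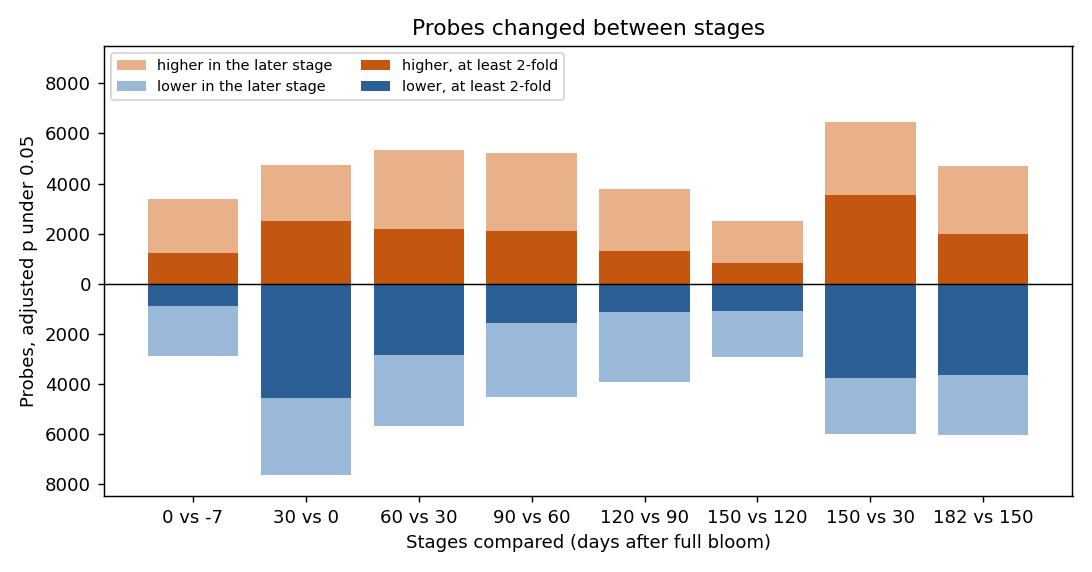
Number of probes with limma's adjusted p under 0.05 (y axis) in each comparison (x axis, stages in DAFB), higher above and lower below the zero line, with changes of at least 2-fold in the darker colour. In the main fit the fewest changed from 120 to 150 DAFB, 5435, and the most from 30 to 150 DAFB, 12485. This order depended on the processing. With the slide as a random block the fewest changed in 0 vs -7 DAFB, 3204, and with normexp the most in 30 vs 0 DAFB, 13577.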

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

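The levels of the named probes and 4 array measures were examined at 60 DAFB, the only stage with 4 arrays. None of these 32 sets of values held an array that stood apart by Dixon's test, which flags about 1 set in 20 by chance. Groups of 3 arrays were not tested.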

How the results depend on the processing

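Of 355 alternative counts of changed probes, 340 lay within 1.5 times the main count. Most of the 355 came from leaving out 1 array, and 0 of the 15 counts outside that range did. The measure ignores direction: spike-in scaling in 60 vs 30 DAFB lay within it, with 2.65% of changed probes higher against 48.3%. Normexp on the median signal, spike-in scaling, fits within a scan day, the fits without 2 arrays picked by eye and without the 3 arrays of lowest quality weight, the 4-fold minimum and the looser detection rule were chosen after seeing the data. With a 2-fold minimum, which by construction calls fewer, 2114 probes changed in 0 vs -7, 7100 in 30 vs 0, 5054 in 60 vs 30, 3708 in 90 vs 60, 2431 in 120 vs 90, 1908 in 150 vs 120, 7315 in 150 vs 30 and 5616 in 182 vs 150 DAFB. Spike-in scaling gave 11150 in 0 vs -7, 4618 in 120 vs 90, 2029 in 150 vs 120 and 7145 in 182 vs 150 DAFB. The slide as a random block, with a consensus correlation of 0.427, gave 3204 in 0 vs -7 and 4626 in 120 vs 90 DAFB, and the fit on the compared arrays alone gave 2484 in 150 vs 120 DAFB. Apart from the 2-fold minimum, whose fewer calls follow from its construction, the cause was not tested. Leaving out each of the 25 arrays gave 16816 to 16883 probes over all stages, 4897 to 7090 in 0 vs -7, 11705 to 12724 in 30 vs 0, 10157 to 11578 in 60 vs 30, 8628 to 10319 in 90 vs 60, 6536 to 8206 in 120 vs 90, 4629 to 5678 in 150 vs 120, 11768 to 12893 in 150 vs 30 and 9823 to 11211 in 182 vs 150 DAFB. Without the 3 arrays of lowest weight no count of changed probes moved by over 1.5 times, with 4725 in 150 vs 120 and 7908 in 0 vs -7 DAFB. Sets by stage and detection counts were less stable: 101 of their alternative values moved by over 1.5 times and 591 did not. All 32 named results kept direction and an adjusted p under 0.05 in limma over 1219 alternative values, with a highest adjusted p of 0.00052. They had been picked from these same arrays as the largest changes without overlap among probes measured on both sides, so this gives no independent support. Most of the alternative values came from leaving out 1 of the 25 arrays, and sizes of change were not compared. With the replicate number as a block 12390 probes changed in 150 vs 30 DAFB against 12485, and 6120 in 0 vs -7 DAFB against 6288, and no count moved by over 1.5 times. In no comparison did every array correlate best with its own number. Gene list alternatives were not run because no list could be matched, and scan day as a block could not be fitted. Signal over background limits the dimmer probes, and 11779 probes were well above background on all arrays.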

Other observations

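The tests in this part on the brightest probes, on the bound of falls at 182 DAFB, on the bound of rises from 0 to 30 DAFB, on extraction, on name classes and on changes shared between comparisons, and the bootstrap interval on probe pairs, were chosen after the results were seen. The bound for the few bright probes was reset more than once after the value was seen, and is now the rise that would halve the signal of all other probes. The test of lower sensitivity at 182 DAFB replaced one on the spike-in controls, which had left it open but could not decide, since the controls would lose signal with the probes.

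The log2 changes of 0 vs -7 and 182 vs 150 DAFB, which share no array, correlated with Pearson's r of -0.077 and Spearman's rho of -0.146 over 17014 probes, which are not independent replicates. At a 2-fold minimum 454 probes rose around bloom and fell in ripening, where independent lists would share 265.2, and 184 rose in both against 143.4. For 0 vs -7 with 150 vs 30 DAFB r was -0.055 and rho -0.039, with 461 probes that rose and then fell against 274.1 and 323 that fell in both against 194.0. Changes of 120 vs 30 DAFB correlated with those of 182 vs 150 DAFB with an r of 0.053 and a rho of 0.131: 1113 probes fell in both against 739.1 for independent lists, and 609 rose in both against 398.6. Each of the 4 combinations of direction exceeded its independent value in these 3 pairs, but not in 30 vs 0 with 182 vs 150 DAFB, where 923 probes fell in both against 981.6.

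Probes of the DIT class and those named by sequence accessions rose more often than they fell in 182 vs 150 DAFB: 245 of 734 DIT probes rose and 150 fell, and 140 of 441 accession probes rose and 93 fell. By limma's camera the adjusted p was 0.0129 for DIT and 0.0144 for accessions with the preset correlation of 0.01. With an estimated correlation it was 0.59 for each. In 150 vs 120 DAFB 115 accession probes rose and 52 fell, with an adjusted p of 0.00216, and 0.679 with an estimated correlation. In 60 vs 30 DAFB 627 of 2689 NLE probes rose and 1147 fell, with an adjusted p of 0.0247, and 0.247 with an estimated correlation. No class call held with an estimated correlation.

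At 182 DAFB 2248 probes were at least 2-fold below each other stage and 961 above. The 100 brightest probes held 0.463 percentage points more of the signal at 182 than at 150 DAFB (summed SD 1.46). Halving all other probes would need a rise of 38.42, a bound reset after the value was seen. This test could not decide whether a few bright probes taking the signal lowered the other probes. Levels are relative to a percentile of the same array, which such a loss would lower together with those probes. The test of lower sensitivity could not decide either. The median lower bound of the fall from the next lowest stage was 1.65 on the log2 scale (bootstrap SD 0.0275) and at least 2-fold for 1817 probes. However, 1231 of the 2248 were well above background on each 182 DAFB array. Their bound is their own fall, at least 2-fold by selection, so the median had to be at least 2-fold. For these 1231 the fall was measured above background, whereas 870 others were so on no 182 DAFB array. Lower sensitivity may account for part. The 182 DAFB arrays had fewer spots well above background (29655 to 30079) than the 150 DAFB arrays (31036 to 34134). The scaling could account for the excess of low over high probes, since their ratio fell to 0.772 with median scaling, against 1.20 with quantile normalization and 1.59 with spike-in scaling, although 1547 to 1723 probes were lowest at 182 DAFB under these 3. Ripening and cold storage, which the design joins, stay open and untested apart from each other. Slide cannot be told apart from stage here either: slide 12 held all 182 DAFB arrays, and slides 10 and 11 held those of 150 DAFB.

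The 2 probes of a clone often disagreed where 1 probe's name ended in tc: over the 25 arrays the median correlation of tc with mR2007a probes was 0.699 over 2516 clones, with 187 below -0.3, against 0.991 for mm with mR2007a probes over 1802 clones. Among clones with both probes well above background on all arrays the gap was 0.214 (bootstrap 95% interval 0.188 to 0.232), and among those with both probes ranging at least 4-fold it was 0.146 (0.128 to 0.166). Dim signal as the whole cause is argued against, narrowly: the gap exceeded the bound of 0.2 set beforehand by more than its bootstrap SD of 0.0117, while the 95% interval, added after the value was seen, reaches below the bound. Little change over the stages stays open, since 0.146 lies between the bounds of 0.1 and 0.2, and either may account for part of the gap. Probe orientation or sequence was not analysed here, and no biological explanation was tested.

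Of the 862 probes detected at 30 and not at 0 DAFB, the median lower bound of the log2 rise was -0.071, so a level as at 30 DAFB would have lain near the detection limit of the 0 DAFB arrays. Lower sensitivity at 0 DAFB may thus account for much of this count, and less readily for the 276 probes whose bound was at least 2-fold. It is not excluded for them, since the bound uses the lowest signal well above background on each array. A probe's own limit may lie higher. The 75th percentile relative to the spike-in controls was -3.51 ± 0.57 (SD, n = 3) at 0 DAFB and -2.04 ± 0.27 at 30 DAFB. RNA extraction, input and tissue label cannot be told apart from stage, because 0 arrays of 30 DAFB used the extraction of 0 DAFB.

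Other splits of the arrays bear on chance. For 60 vs 30 DAFB only 1 of 35 splits, the real one, gave as many changed probes (11933, highest other 0), and for 90 vs 60 DAFB also 1 of 35 (11528, highest other 361). The share of 0.029 is the smallest that 35 splits allow. It lies under the bound of 0.05 and argues against a chance assignment of these arrays, but does not exclude it. The shares were not corrected for the number of tests. Over all stages 1 of 100 splits, the real one, gave as many (16865, highest other 4222), a share of 0.01 with the same reading. The splits treat arrays as exchangeable and exclude no effect of slide or of fruit: the 30 DAFB arrays all lay on slide 9 and the 90 DAFB arrays on slide 3, and arrays of a slide had a consensus correlation of 0.427. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05: the real split gave 5317 in 0 vs -7 DAFB (highest other 3), 12294 in 30 vs 0, 6894 in 120 vs 90, 2484 in 150 vs 120, 11495 in 150 vs 30 and 10095 in 182 vs 150 DAFB (highest other 0 in each of these).

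The 100 brightest probes held 49.5% ± 4.94 (SD, n = 3) of the signal at 0 DAFB, 37.1% ± 2.57 at -7 DAFB and 23.2% ± 0.65 at 150 DAFB. The array 150 DAFB replicate 3 had 34134 spots well above background, and leaving it out gave 9823 changed probes in 182 vs 150 DAFB against 10774. Of the 436 outlier spots 237 lay on 0 DAFB replicate 1.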
